A study of Mus musculus with 4 samples.

How the data were processed

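The data are RNA sequencing counts of sorted mouse megakaryocytes from 4 groups of 1 library each, PF4-Cre wild-type, PF4-Cre knockout, ROSA-Cre wild-type and ROSA-Cre knockout, with groups taken from the sample titles. Per the labels' protocols, RNA was extracted with the MagMax-96 kit and libraries were made with a stranded TruSeq mRNA kit for paired-end sequencing. The submitters' processing notes name TopHat2 2.0.10, SAMtools, HTSeq and DESeq and the builds mm10 and GRCm38, without saying how they were set. The authors deposited 1 table per library with raw HTSeq read counts per Ensembl gene, not normalised. The annotation release, the strand setting of the counting and any pooling of mice are not given in the sources used here. Reads of a gene and an overlapping or antisense partner can therefore not be told apart with certainty, and genes with near-identical copies (histones, immunoglobulins, globins, tubulins, Hspa1a and Hspa1b, H2-Q1, Tgtp1, Zfp990, Rprl3 and Rpl34-ps1) are uncertain wherever the counting could split or drop their reads, as is Clec9a, which overlaps Clec1b.

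Each file held 41214 gene identifiers and 5 lines of HTSeq categories, which stayed out of library sizes and tests. Reads with no gene made up 32.0%, 36.1%, 34.9% and 36.2% of uniquely aligned reads in the order PF4-Cre wild-type, PF4-Cre knockout, ROSA-Cre wild-type and ROSA-Cre knockout, and ambiguous reads 0.489%, 0.448%, 0.531% and 0.532%. Symbols were found for 40254 identifiers and GRCm38 coordinates (GENCODE release M21) for 40340, and 960 identifiers had no symbol. Gene counts per library were 61652843, 59595680, 24869421 and 21835165, a 2.6-fold difference in depth between the models. Counts of the repeat-like genes Gm26917 and Gm42418 took 0.214%, 0.223%, 1.78% and 0.932% of gene counts, and the small RNA genes Rn7sk, Rpph1 and Rmrp 1.74%, 1.94%, 2.40% and 3.33%. Mitochondrial genes took 0.446%, 0.476%, 0.259% and 0.32%.

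The genotype effect and the Cre model effect were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr by genotype (minimum count 10), a model with Cre model and genotype, quasi-likelihood F-tests with default settings and Benjamini-Hochberg adjustment at 0.05. This left 15063 genes, 1 residual degree of freedom per gene and 6.25 prior degrees of freedom, with a common biological coefficient of variation of 16.1%. The single residual degree is the disagreement between the models, moderated across genes. Standard errors are the log2 fold change over the square root of F. Within a model, where each group has 1 library, ratios of normalised counts were given with a pseudocount of 1 on the log2 scale and a 95% Clopper-Pearson interval. Intervals and the floor of 3 counts per library cover counting error only, since reads without molecular identifiers are not independent molecules. Agreement between the models was described by correlations across genes and by overlaps beside the number that independent lists would share.

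Before the data were examined, 42 gene lists were fixed. They were tested with camera (limma 3.58.1) on edgeR's count object, whose counts are turned into z-scores. It used a preset correlation of 0.01 and, separately, the correlation estimated from the data, with adjustment over the 42 lists. Only the run after the GC and length correction used log2 CPM, with prior count 1. The median ratio of each list in each model was ranked among 10000 random lists matched in 20 expression bins. The reported repression targets were listed from general knowledge of GFI1 and GFI1B, without use of these libraries. Gfi1b, Klf1, Gata2, Hoxa9, Csf2rb, Ctsg, Alas2 and some other genes stand in more than 1 list. The result of 1 list and some single genes are not reported here. The rule for named genes was also fixed then. It took Gfi1b and Gfi1 always, and 12 genes each way for the genotype effect and 6 each way for the Cre model effect by fold change, past the test, in the same direction in both pairs and with a mean of at least 5 CPM. It also took 5 genes each way within each model with at least 100 counts, 5 each way among genes changed in opposite directions, and in each list up to 4 members with the smallest p-values and the most abundant marker of each other cell type. Gp5, Gp9, Pf4, Ect2, Cd48 and S100a8 were named after their values were seen.

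Alternatives fixed beforehand were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, a mean of at least 5 CPM, the older quasi-likelihood method, a robust prior, a model without the other term, the fit without each library in turn, and the fit without erythroid, neutrophil and mitochondrial genes. For the size rule they were limits of 1.5-fold and 4-fold, other scalings, a pseudocount of 5 and other count filters. Alternatives added after seeing the data were a GC and length correction (natural splines with 4 degrees of freedom per trend on GC percent and log2 exonic length, fitted per library and used as an offset), thinning of all libraries to 21835165 counts, leaving out genes on chromosomes X and Y, and, for the Cre model effect, leaving out erythroid, neutrophil and mitochondrial genes. GC content was known for 14949 genes, 99.2% of those tested. The division of neutrophil genes into early and late granule genes was also made after seeing the values.

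The scripts were tested on simulated counts for the 15063 genes with 200 genes changed in both models. For the genotype effect edgeR recovered 65 of 100 genes changed 2-fold and 89 of 100 changed 4-fold, with 17 unchanged genes among its calls (9.9%), and DESeq2 recovered 59 and 77 with 3 unchanged genes (2.2%). The size rule recovered 96 of 100 genes changed 4-fold in PF4-Cre and 91 of 100 in ROSA-Cre, and also took 4.23% and 4.1% of unchanged genes. Numbers were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.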

Results

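RNA was sequenced from megakaryocytes, the bone marrow cells that shed platelets, taken from C57Bl/6 mice aged 8 weeks. The cells had been sorted from leg and arm bones as negative for lineage markers and positive for cKit, CD41 and CD61, the last pair being subunits of the platelet fibrinogen receptor. Gfi1b, the gene under study, encodes a zinc finger repressor needed for megakaryocyte and red cell development. It was labelled wild-type or knockout in 2 Cre models, PF4-Cre and ROSA-Cre, which gives 4 groups of 1 library each. Pf4, the platelet factor gene named in the first model, is active in megakaryocytes, and the labels say no more of the ROSA-Cre allele. Gene counts totalled 61652843 in the PF4-Cre wild-type library, 59595680 in the PF4-Cre knockout, 24869421 in the ROSA-Cre wild-type and 21835165 in the ROSA-Cre knockout. A count of 0 therefore allowed a level of up to 0.0487, 0.0503, 0.121 and 0.137 CPM (counts scaled to the library total) in that order, while the CPM of genes below are scaled to TMM-normalised library sizes. The labels do not say whether a library came from 1 mouse or a pool. For each gene the p-values below rest on how far the genotype change disagreed between the 2 Cre models, moderated across genes. Each model acted as the replicate of the other (n = 2 libraries per genotype), and the average difference between models did not enter that spread.

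Gfi1b itself had a higher count in the libraries labelled knockout, in both models. The gene (ENSMUSG00000026815, chromosome 2 from 28609450 to 28621982 on the minus strand of GRCm38, protein coding) had 10137 counts or 169.6 CPM in the PF4-Cre wild-type library and 84744 counts or 1401 CPM in the PF4-Cre knockout. The ROSA-Cre libraries held 5864 counts (238 CPM) and 55122 counts (2462 CPM). Normalised ratios were 8.26 in PF4-Cre (95% Clopper-Pearson counting interval 8.09 to 8.43) and 10.3 in ROSA-Cre (10.1 to 10.6), and the log2 fold change over both models was 3.21 (SE 0.17, adjusted p = 0.000142, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A gene count sums the reads of all exons, and the labels do not say which exons were deleted, so the count alone cannot show that the labels are right. Because it runs against what a loss of transcript would give, knockout means labelled knockout throughout, and every direction below rests on those labels. Gfi1 (ENSMUSG00000029275, chromosome 5 from 107716657 to 107726036, minus strand), the paralogue of Gfi1b with a nearly identical DNA-binding domain, rose as well. Its counts went from 471 to 2416 in PF4-Cre (ratio 5.07, interval 4.59 to 5.61) and from 198 to 2128 in ROSA-Cre (11.8, 10.2 to 13.7), a log2 fold change of 2.92 (SE 0.28, adjusted p = 0.00129 by the same edgeR test).

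The first comparison asked which transcripts differed between the genotypes in both Cre models. In libraries labelled knockout 1904 of 15063 tested genes were higher and 1444 lower (edgeR's quasi-likelihood test with the Cre model as a term, Benjamini-Hochberg adjusted), and rises were larger than falls. Among genes past the test, 1271 rose and 291 fell at least 2-fold, and 274 rose and 8 fell at least 8-fold. Tmem215, a transmembrane protein gene, had the largest rise among the named genes, from 37 to 27630 counts in PF4-Cre and from 14 to 7168 in ROSA-Cre (log2 fold change 9.39, SE 0.20, adjusted p = 3.81e-06). Plagl1, an imprinted zinc finger transcription factor, rose by 7.50 (SE 0.18), Cacna1e, a voltage-gated calcium channel subunit, by 6.74 (SE 0.28), and the long noncoding RNA Miat by 6.69 (SE 0.37). Rasgrp3, an exchange factor for Ras-family GTPases, rose by 6.43 (SE 0.31), Lamb2, a laminin chain of basement membranes, by 6.40 (SE 0.30), and Palld, an actin-bundling protein, by 6.10 (SE 0.45). The wild-type libraries held 1 to 7 counts of Adamts9, a secreted metalloprotease, of Cdhr1, a cadherin of photoreceptors, and of Colec11, a collectin of the complement system. Their ratios were 302 (counting interval 118 to 1111), 441 (151 to 2141) and 162 (78.5 to 405) in PF4-Cre and 279 (49.7 to 11070.0), 90.7 (24.7 to 755) and 268 (73.7 to 2216) in ROSA-Cre.

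The falls named next were among the largest in genes with a mean of at least 5 CPM and the same direction in both models. Serpinb10, a serpin of blood cells, fell by 2.48 on the log2 scale (SE 0.73, adjusted p = 0.0489), and Dok2, an adaptor that restrains receptor tyrosine kinase signalling, fell by 2.24 (SE 0.51). Cnr2, the cannabinoid receptor of immune cells, fell by 2.17 (SE 0.38), and Nrarp, a feedback inhibitor of Notch signalling, fell by 1.94 (SE 0.40). These falls were unlike in size between PF4-Cre and ROSA-Cre. They were 2.13-fold and 35.9-fold for Serpinb10, 2.11-fold and 11.9-fold for Dok2, 2.52-fold and 9.10-fold for Cnr2, and 2.32-fold and 8.64-fold for Nrarp. Mpo, the myeloperoxidase of neutrophil granules, fell from 41584 to 11790 counts in PF4-Cre and from 17505 to 4017 in ROSA-Cre (log2 fold change -1.91, SE 0.13, adjusted p = 0.000299). Emid1 fell by 2.01 (SE 0.35), Mdga1 by 1.94 (SE 0.26), the lipoprotein receptor Lrp8 by 1.90 (SE 0.35) and the nucleoside transporter Slc28a2 by 1.89 (SE 0.29), each of them further in ROSA-Cre than in PF4-Cre. Leaving out the PF4-Cre wild-type, PF4-Cre knockout, ROSA-Cre wild-type or ROSA-Cre knockout library, with the Cre model term dropped, left 506, 1061, 517 and 624 genes (83.4%, 80.5%, 91.7% and 88.8% higher), and all 4 libraries without that term gave 162, of which 158 were higher and 4 lower. With no filter on low counts 1935 genes passed, 72.7% of them higher. A GC and length correction gave 43.1% higher among 3520, against 56.9% in the counts above. It also moved the median log2 fold change of all tested genes from -0.0233 to -0.105. The change in the share higher can therefore not be credited to GC and length alone, since that shift was not separated from it.

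**Figure D1:**
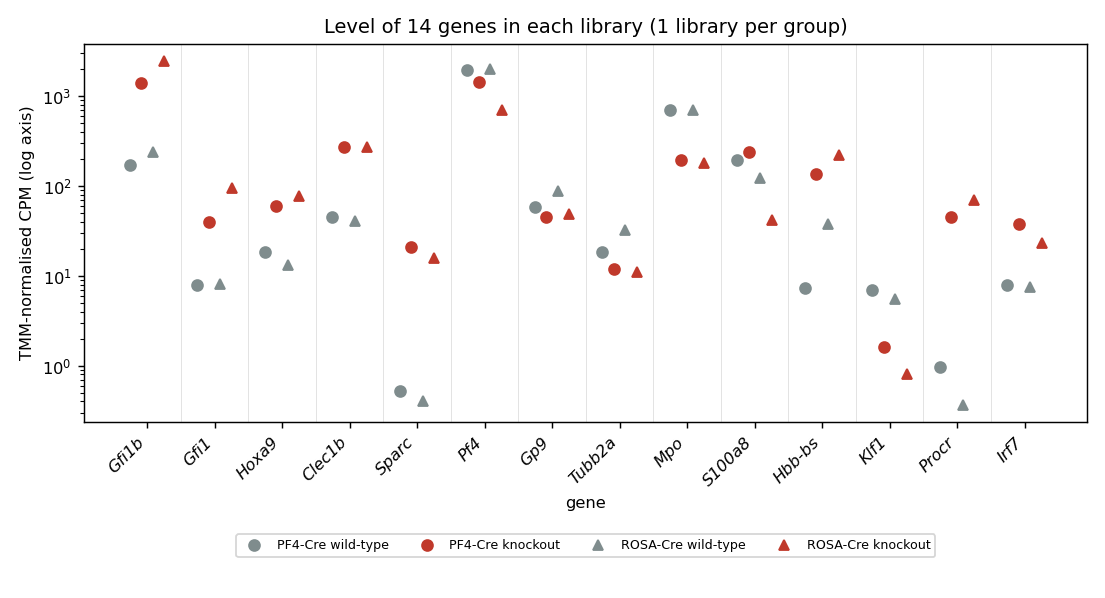
Level of 14 genes in each of the 4 libraries, in TMM-normalised CPM on a log axis, 1 point per library (circles PF4-Cre, triangles ROSA-Cre, grey wild-type, red labelled knockout). Gfi1b stood at 169.6 and 238 CPM in the wild-type libraries and at 1401 and 2462 CPM in those labelled knockout.

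Of 42 gene lists fixed before the data were examined, 21 passed camera, limma's competitive gene set test, with a preset correlation of 0.01 between genes. With the correlation estimated from the 4 libraries none did, and 0 lists had an unadjusted p under 0.05. In the 14 tested genes reported elsewhere as repressed by GFI1 or GFI1B, 4 rose and 0 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.000452, and adjusted p = 0.77 with an estimated correlation). Those 4 were Gfi1b, Gfi1, the homeobox gene Hoxa9 (log2 fold change 2.10, SE 0.22) and the cytokine signalling inhibitor Socs1 (0.98, SE 0.26). The list holds Gfi1b itself, and the median of its 13 other genes, 0.386, lay inside the range of matched random lists (-0.35 to 0.43), as did the list's medians within PF4-Cre (0.26, with a range up to 0.31) and ROSA-Cre (0.47, up to 0.48). After a GC and length correction the list was not called (camera adjusted p = 0.0771). That run tested log2 CPM rather than z-scores, so the loss cannot be credited to the correction alone. Of 15 genes of the LSD1-CoREST complex and its partners, the corepressor that GFI1 proteins recruit, 1 rose, Phf21a (0.66, SE 0.14), and 1 fell, Rcor2 (-0.62, SE 0.16), the same over the list alone. That list did not pass camera (adjusted p = 0.949), and its median of -0.06 and mean of 0.04 had opposite signs.

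Genes of megakaryocytes and platelets went both ways. Among 29 surface receptors 8 rose and 7 fell (9 and 8 adjusted over the list alone). Clec1b, the podoplanin receptor of platelets, rose from 2714 to 16527 counts in PF4-Cre and from 1011 to 6058 in ROSA-Cre (log2 fold change 2.65, SE 0.13, adjusted p = 0.000107), and the thrombin receptor F2r rose by 1.20 (SE 0.16). Esam rose by 0.96 (SE 0.13), whereas Gp5 and Gp9, parts of the von Willebrand factor receptor and picked here after their values were seen, fell by 1.36 (SE 0.31) and by 0.60 (SE 0.16). In 36 platelet granule genes, 9 rose, Gfi1b among them, and 6 fell (9 and 8 over the list alone). The matrix protein gene Sparc rose from 31 to 1263 counts and from 10 to 352 (5.31, SE 0.31). Slc18a2, the transporter that loads serotonin into dense granules, rose by 1.94 (SE 0.15), and Pf4, singled out after the fact as the promoter's namesake, fell by 0.99 (SE 0.26, adjusted p = 0.0341). Among 45 platelet activation genes 7 rose and 2 fell, the same over the list alone, led by the lipoxygenase Alox12 (3.35, SE 0.16) and, downward, the adaptor Lat (-1.21, SE 0.20). Of 23 integrin subunits, 5 rose and 2 fell, the same over the list alone, with Itgb3, which encodes CD61 of the sort gate, higher by 1.05 (SE 0.18). Of 22 megakaryocyte transcription factors 4 rose and 4 fell, again the same over the list alone, Ets1 by 1.83 (SE 0.14) and Gata2 by 1.44 (SE 0.21) upward, the erythroid factor Klf1 by 2.31 (SE 0.33) and Lyl1 by 0.81 (SE 0.15) downward. None of these 5 lists passed camera (adjusted p = 0.332, 0.0891, 0.103, 0.865 and 0.686). The granule list had a median of -0.04 and a mean of 0.27, and the integrins a median of -0.02 and a mean of 0.19, so their medians and tests differed in sign.

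Of 13 tubulin genes, 0 rose and 6 fell (0 and 8 adjusted over the list alone), with Tuba8 lower by a log2 fold change of -1.86 (SE 0.32), Tuba4a of -0.85 (SE 0.16), Tuba1c of -0.81 (SE 0.13) and Tuba1b of -0.76 (SE 0.12). The list passed camera (adjusted p = 8.69e-05, and adjusted p = 0.77 with an estimated correlation), and these paralogues share sequence, so reads can be split between them. Of 36 microtubule-associated and motor proteins, 7 rose and 4 fell, the same over the list alone, among them Map1a (4.53, SE 0.53) and the kinesin Kif1b (1.02, SE 0.14). In 55 actin and myosin genes, 7 rose and 8 fell (7 and 11 over the list alone), with the severing protein gelsolin, Gsn, higher by 1.25 (SE 0.12), the nonmuscle myosin Myh10 by 1.82 (SE 0.22) and the coronin Coro1a lower (-1.10, SE 0.17). Neither passed camera (adjusted p = 0.835 and 0.0846).

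Genes of DNA replication and division were lower in libraries labelled knockout. In the S phase list 30 of 33 fell and 0 rose (32 and 0 adjusted over the list alone), among them the flap endonuclease Fen1 (-0.78, SE 0.12), the chromatin assembly subunit Chaf1a (-0.76, SE 0.13) and the origin licensing factor Cdc6 (-0.77, SE 0.13). Of 36 genes of G2/M and mitosis, 23 fell and 1 rose (29 and 1 over the list alone). Those that fell included Ube2c (-0.92, SE 0.14) and the mitotic kinase Aurkb (-0.82, SE 0.13), and the one that rose, named after its value was seen, was Ect2, an exchange factor needed for cytokinesis (1.66, SE 0.28). Of 71 histone genes 46 fell and 5 rose (52 and 5 over the list alone), with Hist2h2ab at -1.30 (SE 0.15) and Hist1h4k at -0.90 (SE 0.12), while the linker histone H1f0, which is not tied to replication, and the variant H2afy2 rose by 0.90 (SE 0.12) and 3.81 (SE 0.42). Near-identical histone copies make single members uncertain. Camera gave adjusted p values of 3.08e-12, 4.56e-09 and 3.08e-12 for the 3 lists, and adjusted p = 0.77 with an estimated correlation for each. Of 22 neutrophil and granulocyte precursor markers, 7 fell and 0 rose, also over the list alone, with a median log2 ratio of 0.13 in PF4-Cre and -1.72 in ROSA-Cre.

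Several lists of metabolic and endoplasmic reticulum genes had more members lower than higher. Nuclear genes of oxidative phosphorylation had 22 of 43 fallen and 0 risen (32 and 0 adjusted over the list alone), with Atp5g1 at -0.94 (SE 0.18) and Cox5a at -0.86 (SE 0.17). In the unfolded protein response list 12 of 20 fell and 0 rose (13 and 1 over the list alone), among them the lectin chaperone Calr (-1.01, SE 0.23) and Sdf2l1 (-1.56, SE 0.35). Of 23 cholesterol synthesis genes, 8 fell and 0 rose (10 and 1 over the list alone), with the epoxidase Sqle at -1.04 (SE 0.15). Among 86 ribosomal protein genes 9 fell and 0 rose (0 and 0 over the list alone), Rps2 by 0.64 (SE 0.16). The antioxidant list had 6 of 23 fallen and 1 risen (7 and 1 over the list alone), Gpx1 at -0.74 (SE 0.12) and Nfe2l2, the transcription factor that drives that response, at 0.81 (SE 0.13). In 22 heme and iron genes, 7 fell and 2 rose (9 and 2 over the list alone), with Alas1, the housekeeping first enzyme of heme synthesis, at -0.92 (SE 0.15) and its erythroid form Alas2 at 2.91 (SE 0.47). Camera's adjusted p values were 2.35e-08, 0.000188, 0.000422, 2.9e-05, 0.00973 and 0.0246 in that order, with adjusted p = 0.77 for each under an estimated correlation. Of 22 glycolysis genes 3 rose and 7 fell (5 and 7 over the list alone), such as the mutase Pgam1 (0.92, SE 0.13) and hexokinase Hk3 (-1.29, SE 0.18), and the list did not pass (adjusted p = 0.14). Mitochondrially encoded genes, 2 of 10 higher and 0 lower (2 and 1 over the list alone), did not pass either (adjusted p = 0.954), and the pair that rose were the ribosomal RNAs mt-Rnr1 (0.79, SE 0.14) and mt-Rnr2 (45337 to 66392 counts in PF4-Cre and 7152 to 18152 in ROSA-Cre, adjusted p = 0.0227 by the same edgeR test).

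Of 27 interferon-response genes, 17 rose and 0 fell (18 and 0 adjusted over the list alone), including Ifi44 (3.15, SE 0.23), the transcription factor Irf7 (1.98, SE 0.22), Rtp4 (2.51, SE 0.29) and the RNA sensor Ddx58 (1.34, SE 0.15). Camera gave an adjusted p of 6.18e-08, and adjusted p = 0.77 with an estimated correlation. Markers of dendritic cells, some of which secrete interferon, had 3 of 12 higher and 0 lower, also over the list alone, namely Clec9a (2.88, SE 0.18), Pacsin1 (2.58, SE 0.44) and the list's most abundant gene Tcf4 (0.56, SE 0.13), without passing camera (adjusted p = 0.107). The annotated span of Clec9a (chromosome 6, from 129408862 to 129424763) overlaps that of Clec1b (129397297 to 129409335) on the same strand, and Clec1b was more abundant and rose by similar ratios, 6.02 and 6.59 against 6.39 and 8.69, so Clec9a is uncertain. In the JAK-STAT list 9 of 25 rose and 1 fell (9 and 3 over the list alone), with Socs2, a feedback inhibitor, at 2.26 (SE 0.38), the cytokine receptor chain Csf2rb at 1.42 (SE 0.17) and the adaptor Sh2b3 at 1.17 (SE 0.14). Its camera call (adjusted p = 0.0363, and adjusted p = 0.77 with an estimated correlation) ended without the Cre model term (0.0843). It was also absent after the GC and length correction (0.0632), a run on log2 CPM rather than z-scores. Among 10 MHC class II genes, 1 rose, H2-Ob (0.68, SE 0.16), and 0 fell, also over the list alone (adjusted p = 0.865).

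Genes that mark stem and progenitor cells rose in 12 of 28 cases and fell in 1 (14 and 1 adjusted over the list alone). Procr, the protein C receptor that marks long-term stem cells and endothelium, rose from 58 to 2757 counts in PF4-Cre and from 9 to 1578 in ROSA-Cre (6.15, SE 0.37, adjusted p = 0.000198). Fgd5 rose by 3.73 (SE 0.25) and the cell cycle inhibitor Cdkn1c by 2.83 (SE 0.34), while Cd48, which stem cells lack and the only gene of the list to fall, stood at -0.66 (SE 0.17) and was named after its value was seen. Angpt1, the most abundant gene of the list, had a log2 fold change of 0.11 (SE 0.22, adjusted p = 0.762). In the TGF-beta and BMP list 10 of 22 rose and 1 fell, the same over the list alone, with the receptors Bmpr2 (1.86, SE 0.18) and Tgfbr1 (1.10, SE 0.18) and the latency protein Ltbp1 (1.25, SE 0.12). Of 24 p53 targets and apoptosis genes, 8 rose and 3 fell (12 and 4 over the list alone), such as Trp53inp1 (2.34, SE 0.16), the death receptor Fas (1.69, SE 0.27) and the BH3-only gene Bcl2l11 (1.45, SE 0.21). These 3 lists passed camera (adjusted p = 2.13e-06, 0.00684 and 0.00918), with adjusted p = 0.77 for each under an estimated correlation. Among 24 Wnt genes, 6 rose and 3 fell, the same over the list alone, the ligand Wnt10b by 5.74 (SE 0.31) and the receptor Fzd1 by 3.34 (SE 0.51), whereas Ccnd1, cyclin D1, fell by 1.71 (SE 0.23). That list did not pass (adjusted p = 0.313). Of 12 endothelial and stromal markers 3 rose and 3 fell, also over the list alone (adjusted p = 0.361): Plvap, a protein of endothelial pores, rose by 4.74 (SE 0.33) and Emcn by 2.80 (SE 0.32), Col1a2, a collagen of stromal cells, fell by 1.63 (SE 0.33), and the most abundant, the VEGF receptor Kdr, stood at 0.41 (SE 0.24).

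Markers of other blood cells were counted to show what the sorted fraction held. Of 22 neutrophil and granulocyte precursor markers, 7 fell and 0 rose, among them the granule proteases Ctsg (-1.98, SE 0.13) and Elane (-1.81, SE 0.13) and the precursor gene Ms4a3 (-1.67, SE 0.14). Erythroid markers had 12 of 29 fallen and 5 risen (14 and 5 adjusted over the list alone). Klf1, Tspan33 (-2.20, SE 0.35), Car1, the red cell carbonic anhydrase (-2.04, SE 0.31), and the blood group gene Rhd (-2.44, SE 0.59) were among those that fell. The adult globin genes Hbb-bs (3.36, SE 0.36), Hba-a1 (2.82, SE 0.33) and Hba-a2 (3.18, SE 0.38) rose, and Car2, the most abundant of the list, stood at -0.27 (SE 0.12, adjusted p = 0.141). Among 24 monocyte and macrophage markers 7 fell and 0 rose (9 and 0 over the list alone), including Irf8 (-1.05, SE 0.26), Csf1r (-1.16, SE 0.30) and Cd5l (-1.66, SE 0.35), and the most abundant, the lysozyme gene Lyz2, stood at -0.14 (SE 0.15). Of 17 B lineage markers 2 fell and 0 rose (1 and 0 over the list alone), the heavy chain Ighm by 0.81 (SE 0.13) and Dntt by 1.04 (SE 0.28). Camera's adjusted p values were 4.56e-09, 0.013, 0.00693 and 0.0314, and with an estimated correlation adjusted p = 0.77 for 3 of them and adjusted p = 0.82 for the erythroid list. In the basophil, mast cell and eosinophil list 3 of 19 rose and 3 fell, the same over the list alone (adjusted p = 0.647), Csf2rb upward and the histamine-forming enzyme Hdc (-1.38, SE 0.19) and Siglecf (-1.74, SE 0.32) downward. Its most abundant gene, the eosinophil granule gene Prg2, fell by 1.18 (SE 0.29), but stood at 0.35 without the PF4-Cre knockout and at 2.18 without the ROSA-Cre wild-type library. Of 7 T, NK and innate lymphoid markers 0 passed the edgeR test, also over the list alone, with 4 at an unadjusted p under 0.05 and 1 past DESeq2's adjusted threshold, and Nkg7, the most abundant, stood at -0.66 (SE 0.22, adjusted p = 0.0723).

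**Figure D2:**
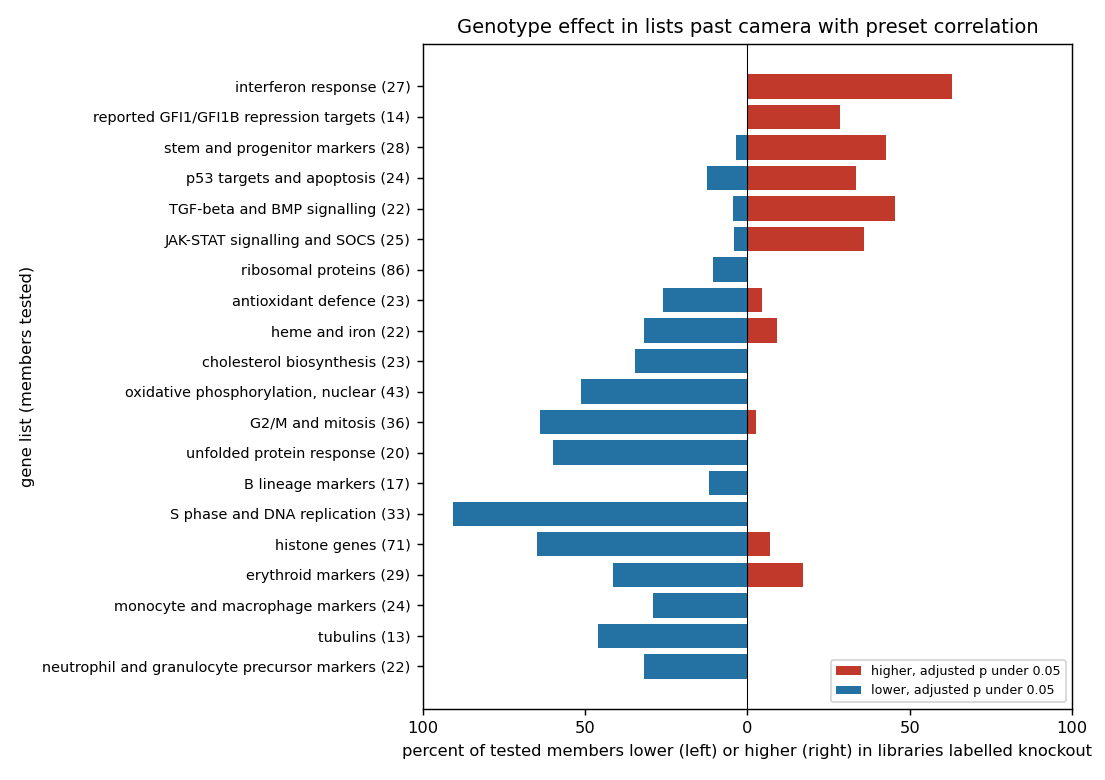
Percent of the tested members of each list that were lower (blue, left) or higher (red, right) in libraries labelled knockout, for 20 of the 21 lists past camera with a preset correlation, with the number of members in parentheses. The S phase list had 30 of 33 lower and the interferon list 17 of 27 higher, and none of the lists passed with an estimated correlation.

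Among immediate early and heat shock genes 6 of 24 rose and 2 fell with genotype (7 and 3 adjusted over the list alone, camera adjusted p = 0.865). The inducible chaperones Hspa1b and Hspa1a, near-identical copies, fell by 1.67 (SE 0.14) and 1.55 (SE 0.22), and Ier3 rose by 1.45 (SE 0.26). The median of that list was 0.19 and its mean -0.02. Of 19 serpin, kallikrein and granzyme genes, 7 rose and 1 fell (8 and 1 over the list alone, camera adjusted p = 0.123), led by the collagen chaperone Serpinh1 (2.73, SE 0.49). Cathepsins had 4 of 14 higher and 2 lower, the same over the list alone (adjusted p = 0.86), with Ctso higher by 1.05 (SE 0.18). Of 10 regulators of G-protein signalling 2 rose and 0 fell, also over the list alone (adjusted p = 0.835), Rgs10 by 0.69 (SE 0.14) and Rgs3 by 1.53 (SE 0.31), with a median of -0.04 and a mean of 0.25. Of the 6 sex-linked genes 0 passed the edgeR genotype test, over all genes or over the list alone, with 1 at an unadjusted p under 0.05 and 0 past DESeq2's adjusted threshold (camera adjusted p = 0.596). That does not show that sex makeup was the same in both genotypes of each model.

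Within PF4-Cre the knockout library was set against 1 wild-type library, so the difference has no replicate check and no p-value is given. Genes counted as changed by size had a ratio of at least 2 and a 95% counting interval excluding 1, which gave 1443 higher and 403 lower of 15063. In simulated counts the same rule took 628 of 14863 unchanged genes, both directions together, so part of these calls, and many of the falls, could be false. With at least 100 counts in the knockout library, the largest rises were in Tmem215 (738-fold, interval 535 to 1048), Plagl1 (199.8-fold, 153 to 265), Cdhr1, Adamts9 and Col17a1, a collagen of epithelial anchoring structures. Col17a1 went from 0 to 438 counts, at least 144-fold higher against the floor of 3 counts in the library. Among genes with at least 100 counts in the higher library, the largest falls were in Hist1h4m (1592 to 6 counts), the immunoglobulin segments Ighv6-3 (180 to 10 counts) and Iglc2 (101 to 16), the niche chemokine Cxcl12 (336 to 43, 7.91-fold, interval 5.75 to 11.1) and the eosinophil gene Prg3 (141 to 18). Histone and immunoglobulin genes share sequence with other copies and are uncertain. With a 1.5-fold limit 3404 genes counted as changed, with a 4-fold limit 597, and with at least 100 counts in the higher library 1141, against 1846.

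Within ROSA-Cre, again without a replicate check, 1908 genes were higher and 1008 lower by the same size rule, which took 610 of 14863 unchanged genes in simulated counts. Il1rapl2, an interleukin receptor accessory gene on chromosome X, went from 0 to 315 counts (115-fold higher against the same floor of 3 counts per library, and at least 93.3-fold by the counting interval). By that interval the protease inhibitor gene Pi15 rose at least 78.4-fold (0 to 265 counts), Prrt4 at least 40.3-fold (0 to 137) and Zfp37 at least 39.4-fold (0 to 134). Against the floor those rises were 97.1-fold, 50.2-fold and 49.1-fold, and Tmem215 rose 563-fold (335 to 1030.0). Under the same limit of 100 counts, the largest falls were in the immunoglobulin genes Igha, from 601 to 1 count, and Iglc2, from 194 to 4, in Ank3, an ankyrin of the membrane skeleton, from 221 to 3 (67.0-fold, interval 22.6 to 328), in Serpinb10, from 1184 to 30, and in Rhd, from 105 to 3 (31.8-fold, 10.6 to 157). Igha, made by plasma cells, fell 547-fold (interval 97.8 to 21630.0) here and 1.24-fold (1.13 to 1.36) in PF4-Cre. Limits of 1.5-fold and 4-fold gave 5290 and 1042 genes, and at least 100 counts 1672, against 2916.

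Gene lists are described within each model by the percentile of their median among 10000 random lists of the same size and expression level. Interferon genes had a median log2 ratio of 0.88 in PF4-Cre and 0.85 in ROSA-Cre, above every random list in both. The S phase list had medians of -0.56 and -0.70 and the histones of -0.71 and -0.59, below every random list. Erythroid markers stood at -0.32 (percentile 0.11) in PF4-Cre and at -2.31, below every random list, in ROSA-Cre. Neutrophil and granulocyte precursor markers had a median of 0.13 (percentile 95.7) in PF4-Cre and of -1.72, below every random list, in ROSA-Cre. Monocyte and macrophage markers stood at -0.35 (percentile 0.19) and -1.15, and megakaryocyte surface receptors at 0.18 (percentile 99.9) and -0.19 (percentile 14.4). Whether these medians differ between the models was not tested, since 4 libraries leave no residual for an interaction.

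The models were then compared across genes, using ratios that share no library. Of the genes counted as changed by size, 1061 were higher in both models, where independent lists would share 182.8, and 199 were lower in both, where 27.0 would be shared. Plagl1 (199.8-fold and 162-fold), Sparc and Clec1b had close ratios in both. Only 41 genes went opposite ways, 22 of them higher in PF4-Cre and lower in ROSA-Cre and 19 the reverse, against 147.6 from independent lists. Across the 15063 genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.715 and Spearman's correlation 0.675, and 76.9% of genes had the same sign. Fold limits of 1.5 and 4 gave 2365 and 421 genes changed the same way and 111 and 4 the opposite way. With at least 100 counts those numbers were 690 and 10 and r was 0.836, against 1260, 41 and 0.715.

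**Figure D3:**
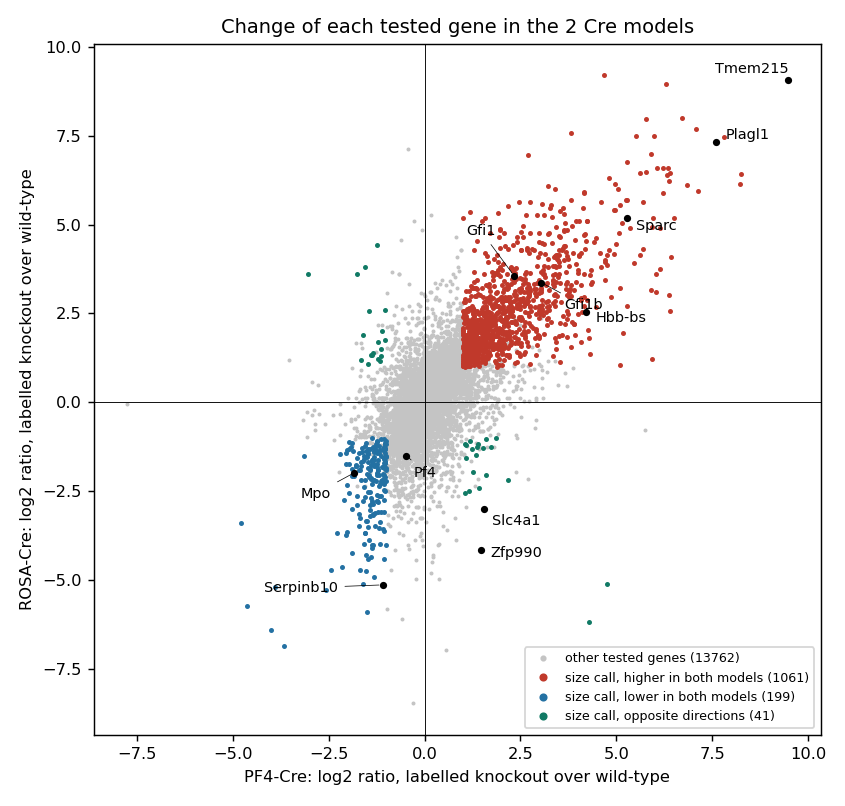
Log2 ratio of labelled knockout over wild-type in PF4-Cre (horizontal axis) and in ROSA-Cre (vertical axis), 1 point per tested gene, coloured where the size rule was met in both models. Of these, 1061 genes were higher in both, 199 lower in both and 41 opposite, and Pearson's r across all genes was 0.715.

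The same fit gave the difference between the Cre models with genotype as a term, 1254 genes higher and 1570 lower in ROSA-Cre (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted, n = 2 libraries per model). Y-linked genes were among the largest differences. Ddx3y, Eif2s3y and Uty had 0 counts in both PF4-Cre libraries, and 1607 and 1791, 1499 and 1656, and 764 and 936 counts in the ROSA-Cre wild-type and knockout libraries. Kdm5d, also on chromosome Y, had 21 and 15 counts in PF4-Cre and 1305 and 1568 in ROSA-Cre. Xist, the RNA of the inactive X chromosome, had 75074 and 77495 counts in PF4-Cre and 2818 and 6334 in ROSA-Cre. Both ROSA-Cre libraries thus held Y-linked and Xist counts, and the PF4-Cre libraries Xist with almost no Y-linked counts, so sex or pooling differed between the models. Xist also differed between the ROSA-Cre libraries while Y-linked counts did not fall, so whether that pair matched in sex makeup is open. Without genes on X and Y, an alternative added after the data were seen, 2783 of 14514 genes differed.

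Stress-response genes were lower in ROSA-Cre. Of the 24 immediate early and heat shock genes, 18 were lower and 0 higher, with a median log2 difference of -1.62 (camera adjusted p = 7.65e-33, and adjusted p = 0.866 with an estimated correlation). Fos, an early response transcription factor, had 9191 and 14608 counts in PF4-Cre and 179 and 171 in ROSA-Cre (log2 difference -4.69, SE 0.19, adjusted p = 7.33e-05). Rgs1, a regulator of G-protein signalling, was at -3.34 (SE 0.18), Slc17a8, a vesicular glutamate transporter, at -3.37 (SE 0.33) and the splicing factor Rbm20 at -3.35 (SE 0.86). Rbm20 had 399 and 13771 counts in the PF4-Cre wild-type and knockout libraries and 85 and 161 in those of ROSA-Cre, so its difference rests on the PF4-Cre knockout. Ear1 and Prg2, genes of eosinophil granules, were higher by 5.66 (SE 0.50) and 4.33 (SE 0.32, adjusted p = 0.00149), both in a basophil, mast cell and eosinophil list with 9 of 19 higher and 3 lower (camera adjusted p = 3.34e-08, and adjusted p = 0.866 with an estimated correlation). Hist1h2al was higher by 5.53 (SE 0.53), while Rprl3, a small structured RNA gene, had 3536 and 1914 counts in PF4-Cre and 1 and 1 in ROSA-Cre, and Zfp990 had 669 and 1876 against 10 and 0. These last 3 belong to families of similar copies and are uncertain. The Cre model cannot be told apart from sex or any batch in which each pair of libraries was handled. After a GC and length correction 159 genes passed, with no filter 1723, and without the genotype term 1, where 2112 had an unadjusted p under 0.05.

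**Figure D4:**
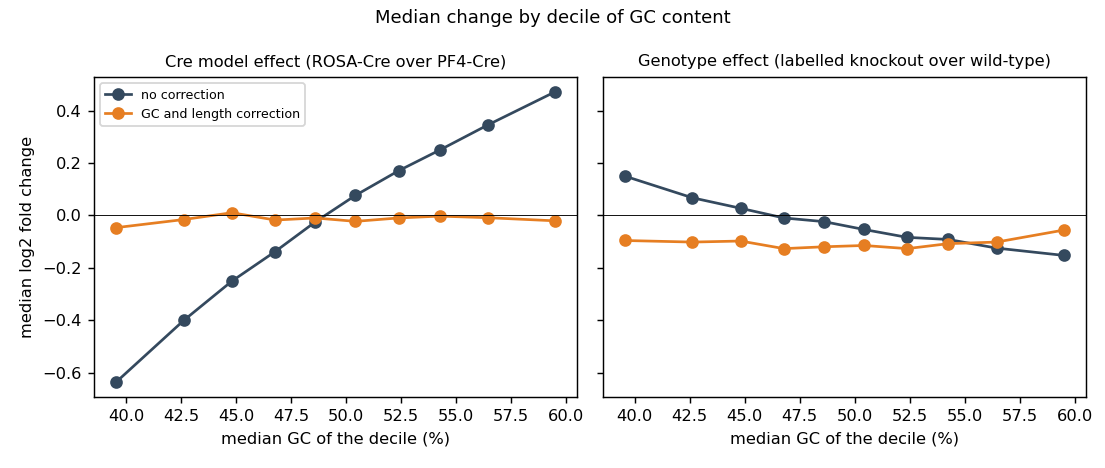
Median log2 fold change of the tested genes in 10 groups of rising GC content (horizontal axis, median GC percent of the group), before and after a GC and length correction, for the Cre model effect (left) and the genotype effect (right). Medians of the Cre model effect lay between -0.64 and 0.47 before the correction and between -0.05 and 0.01 after it. Those of the genotype effect lay between -0.153 and 0.15 before it and between -0.127 and -0.056, all below 0, after it.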

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

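The GC and length correction was added after the data were seen but before its own result, and all other tests below were chosen after their results had been seen, while differences between the models were not tested because 4 libraries leave no residual for an interaction.

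Several genes moved in opposite directions in the 2 Cre models. There were 41 such genes changed at least 2-fold each way. The difference in log2 ratio, ROSA-Cre minus PF4-Cre, was 3.63 for Tgtp1, an interferon-induced GTPase with a near-identical neighbour (ratios 0.487 and 6.18), 2.92 for the MHC gene H2-Q1, 2.85 for the pseudogene Rpl34-ps1, 2.70 for Hist1h2al and 2.43 for the adhesion receptor Adgrl4 (7601 to 3517 counts and 1530 to 3430). For Zfp990, a zinc finger gene of a repeated family, the value of -5.64 is set by the pseudocount, since ROSA-Cre held 10 and 0 counts. That was 3.03-fold lower against the floor of 3 counts per library and at least 2.04-fold lower by the counting interval. In PF4-Cre it rose 2.77-fold (interval 2.54 to 3.03). Slc4a1, the anion exchanger of red cells, stood at -4.56 (92 to 276 counts and 199 to 22), the inflammasome gene Nlrp1b at -3.84, the homeodomain gene Hopx at -3.00 and Lrrc32, which anchors latent TGF-beta, at -2.87. Late neutrophil granule genes had a median difference of -1.98 over 9 genes, all 9 lower in ROSA-Cre than in PF4-Cre. S100a8, 1 of them, went from 11542 to 14363 counts in PF4-Cre and from 2992 to 945 in ROSA-Cre.

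The first pattern is the higher Gfi1b count in libraries labelled knockout. If the deletion acts alike in both models, an exchange of labels within a single model would put 1 ratio below 1 and the other above it, and the smaller was 8.26 (interval 8.09 to 8.43), which excludes that exchange without showing which labels are right. The largest gain of the 5 tested genes within 100 kb, in Gtf3c5, was 1.65% of the gain of Gfi1b in PF4-Cre and 1.09% in ROSA-Cre. That argues against reads running on from a tested neighbour that itself rose as far. Genes below the count filter, unannotated transcripts and run-on without a rise of the neighbour were not covered, so run-on is not excluded. Labels exchanged in both models cannot be told apart from correct ones by the 13 other reported repression targets, whose median of 0.386 lay inside the range of matched random lists (-0.35 to 0.43). A candidate explanation is that the repressor represses its own gene and that the remaining exons are transcribed more without it, which stays open and untested because the deleted exons are not named.

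The second pattern is the fall of early neutrophil granule genes, Mpo, Elane, Prtn3, Ctsg and Ms4a3, with median log2 ratios of -1.72 in PF4-Cre and -1.99 in ROSA-Cre. In PF4-Cre the median of 9 late granule genes was 0.28 (SD 0.16), so they did not fall with the early ones. The early and late genes were divided after their values were seen, so less RNA of mature neutrophils cannot be called excluded there. In ROSA-Cre the median of the late genes was -1.64 (SD 0.32), so there they fell as well. Whether mature neutrophils hold RNA of the early genes was not tested, so the late medians decide nothing on the early fall in either model. Fewer granulocyte precursors in the sorted cells could not be decided. The test assumed that such precursors lack monocyte and B lineage markers, so that those medians stay near 0. They were -0.35 and -0.38 in PF4-Cre and -1.15 and -0.67 in ROSA-Cre, falls smaller than those of the early genes. Whether the precursors lack these markers was not tested, so the medians decide nothing. The sort gate excluded lineage-positive cells and required cKit, CD41 and CD61, but how far it removed granulocyte precursors was not tested. An effect of genotype on the early granule genes within megakaryocytes also stays open and untested.

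The third pattern is the difference between the models that followed GC content (Spearman's correlation across genes 0.589). A correction for GC and length per library left 5.3% of the 2824 Cre model calls in the same direction, with 2997 genes at an unadjusted p under 0.05 against 5407 before it (edgeR's quasi-likelihood test). How far smaller differences and the adjustment each ended calls was not separated. The median size of the 2824 calls went from 0.78 to 0.38 while the median SE went from 0.15 to 0.14, and 50.8% fell below 0.5 of their size, so the GC trend is a candidate source for a part of these differences, with the rest left open. It does not account for the immediate early and heat shock list, whose median went from -1.62 to -1.805 with the correction. With all libraries thinned to the smallest 97.0% of the calls were kept, which argues against depth, while batch and sex go with the model and stay open.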

How the results depend on the processing

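Tests with the GC and length correction, with thinned libraries, without X and Y genes and, for the Cre model effect, without erythroid, neutrophil and mitochondrial genes were chosen after the results were seen.

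The genotype effect of 3348 genes stayed within 1.5 times, from 2738 to 4005, under other normalisation, DESeq2, a higher expression filter, other quasi-likelihood settings, thinning, GC correction and the fits without marker or X and Y genes. It dropped to 1935 with no filter, where 21765 genes were tested and 1901 of the calls were shared, and to 162 without the Cre model term, where differences between the models enter the spread. Leaving out each library in turn, with the lone library of a genotype assumed to vary like the other genotype, gave 506 to 1061 genes. The Cre model effect of 2824 genes ranged from 2566 to 3563 under most of these, but was 1723 with no filter, 1 without the genotype term and 159 after GC and length correction. The cause of the loss with no filter was not tested. Within the models, limits of 1.5-fold and 4-fold gave 3404 and 597 genes in PF4-Cre, 5290 and 1042 in ROSA-Cre, 2365 and 421 changed the same way in both and 111 and 4 changed opposite ways. At least 100 counts in the higher library gave 1141, 1672, 690 and 10, all by construction of the limit. Of the gene lists 21 passed camera, 18 after GC correction, 19 without the Cre model term and 0 with an estimated correlation, which with 1 residual degree of freedom rests on few data (camera found 0 unadjusted p under 0.05, against 23 with the preset correlation). The corrected run tested log2 CPM rather than z-scores, so the change to 18 cannot be credited to the correction alone.

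Of all 3348 genotype calls DESeq2 shared 2822 in the same direction, the GC correction kept 82.8% and the fit with no filter shared 1901. Named genes were mostly picked by fold change and p-value in these same data, which favours stable calls. Among 174 named genes past the genotype test, 165 to 174 kept their call under DESeq2 (166), GC correction (167), the older method (171), a robust prior (165), other size factors and thinning (174). With no filter 151 kept it, without the Cre model term 33, and with 1 library left out 75 to 108. Gfi1b, Gfi1 and all 12 named genes with the largest rises kept their call under every alternative, while 10 of the 12 with the largest falls lost it under at least 1, Mpo and Ctsg being the exceptions. Of the named genes for the Cre model effect, 0 of 6 higher in ROSA-Cre and 1 of 6 lower, Rprl3, kept their call under every alternative, and the other 11 lost it without the genotype term, where genotype differences enter the spread. Without 1 library the log2 fold change of Gfi1b ranged from 2.78 to 3.59. Dropping a library leaves the models unbalanced between genotypes, which by construction turns genes that differ between models. Over the libraries left out, the genotype value ranged from -13.61 to 13.89 for Ddx3y, from -13.51 to 13.77 for Eif2s3y, from -12.53 to 12.94 for Uty, from -6.73 to 6.63 for Kdm5d, from -4.79 to 4.61 for Hist1h2al, from -3.40 to 4.11 for Fos, from -10.73 to 5.28 for Zfp990, from -2.78 to 2.20 for Rgs1, from -9.27 to 8.52 for Rprl3, from -0.25 to 2.39 for Zfp36 and from -4.71 to 2.18 for Prg2, whose call of -1.18 also turned to 0.35 without the PF4-Cre knockout. The genotype call of -0.89 for Rprl3 turned as well, to 8.52 without the PF4-Cre wild-type and to 0.09 without the ROSA-Cre knockout library. Zfp36 turned to -0.25 without the PF4-Cre knockout. Of 44 ratios within a model, 4 moved beyond their counting interval with a pseudocount of 5 and 3 with total counts as the scale. Depth limits low genes most in ROSA-Cre, where 3 counts stand for 0.121 and 0.137 CPM.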

Other observations

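Globin transcripts rose while 12 of 29 erythroid markers fell. Summed over Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2, the adult globin genes, PF4-Cre libraries held 659 counts (11.0 CPM) in wild-type and 10927 (181 CPM) in the knockout, and ROSA-Cre libraries 1466 (59.6 CPM) and 7055 (315 CPM). Alas2, which makes heme for haemoglobin, rose with them (log2 fold change 2.91, SE 0.47), whereas Slc4a1 went from 92 to 276 counts in PF4-Cre and from 199 to 22 in ROSA-Cre. These genes were summed after their values were seen, and no source of the globin reads was tested.

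The ROSA-Cre libraries also had more counts in Gm26917 and Gm42418, genes overlapping ribosomal RNA repeats, 1.78% and 0.932% of gene counts against 0.214% and 0.223% in PF4-Cre. Histone genes, which lack poly(A) tails when made in S phase, had 21 of 71 higher and 3 lower in ROSA-Cre than in PF4-Cre (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted), the opposite of their genotype change. Camera gave that list an adjusted p of 2.34e-06, adjusted p = 0.866 with an estimated correlation and 0.637 after the GC and length correction, which was added after the data were seen. The corrected run tested log2 CPM rather than z-scores, so that change cannot be credited to the correction alone.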
